A study of Canis lupus familiaris with 17 samples.

How the data were processed

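Olfactory epithelium, the sheet of nasal tissue that holds the odour-sensing neurons, was taken from 17 domestic dogs (Canis lupus familiaris), and its polyadenylated RNA was sequenced as paired-end reads on 2 lanes, per the labels' protocols. RNA was isolated with a TRIzol-based column kit and libraries were made with the KAPA mRNA HyperPrep kit. Each sample carries a breed, an age without a stated unit, a weight in kg, a 2-level weight class, a scent code of 0 or 1 whose meaning the labels do not spell out, an RNA integrity number (RIN) and a batch from 1 to 6. Replicate numbers were given in accession order and only name dogs. The protocol states that 4 samples were extracted in 2 separate batches and does not say which. The labels mark 4 libraries as a first replicate: scent_1 replicates 1, 2 and 5 and scent_0 replicate 3. Whether these hold pooled or single extractions is not given in the sources used here, and they include the 3 libraries with the highest totals.

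The count table deposited by the authors holds whole-number reads per feature, with no normalization, for 32912 features in 17 columns. Of these features, 32704 carry Ensembl-style dog gene IDs and 208 are named for a chromosome and a running number, 15 of them for unplaced sequence. A second deposited table holds log2 expression values for 16917 features, and its name states that a batch effect was taken out. The formula behind the deposited log2 values is not given in the sources used here. Their gene means followed log2 CPM (counts scaled to the library total) of the count table with r = 0.9993 across features, and within single libraries r lay between 0.918 and 0.993. Trim Galore 0.3.1, STAR 2.5.3, HTSeq, edgeR, limma and DESeq2 are listed in the submitters' processing notes, without roles or order. Genome build and annotation are not given in the sources used here. Because a batch-corrected value has lost degrees of freedom that a later test does not know of, the log2 table served only as an alternative.

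The files do not pair IDs with gene names. A RefSeq gene table of assembly UU_Cfam_GSD_1.0 was at hand, but 0 of the IDs matched it, and it was used only to count olfactory receptor and protein-coding genes per chromosome. The planned tests of cell type and pathway gene lists, the planned olfactory receptor measures and the planned rule for named genes all need gene names and were not run. In their place, the 208 chromosome-named features were treated as a group and by chromosome, a choice made after the files had been seen. Of the other features, the 2 with the smallest p in each direction among those called were named by ID for the size comparison. Single chromosome-named features are not named, since near-identical copies in a multigene family can share reads.

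Library totals ran from 10536639 to 31637925 counts. Features were kept by edgeR's filterByExpr on the scent groups, with its minimum count of 10, which left 16202 features, 90 of them chromosome-named. Library sizes were scaled by the trimmed mean of M-values (TMM). Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, R 4.3.3) in a model with batch, size class and scent, leaving 9 residual degrees of freedom. Age and the scent by size interaction each added 1 term, leaving 8. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05, and the common biological coefficient of variation was 0.383. Batches 2, 3, 4 and 6 (14 dogs) held both weight classes and batches 1, 3 and 6 (10 dogs) both scent codes. As the 2 factors were fitted together, dogs of the other batches bore on a coefficient through the other factor, except the single dog of batch 5. Sets of at least 3 chromosome-named features were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry.

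For each dog, the TMM-scaled CPM of the chromosome-named features was summed and log2-transformed, and totals by chromosome received 0.5 CPM before the log for the 6 chromosomes, and the unplaced group, with at least 10 such features. The detected number was the number of these features with at least 5 reads after each library had been thinned at random to 10536639 counts. Groups were compared by two-sided exact permutation tests over all 19448 (scent) or 24310 (size) splits. They were compared again over the 60 or 360 splits that keep each batch's numbers, on batch-centred values. The 4 main tests and the 16 tests by chromosome formed 2 families for adjustment. Correlations used 100000 permutations, or all orderings below 10 dogs. Shares of counts in single libraries carry 95% Wilson intervals, which cover counting error only. Computations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

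The count test was tested on simulated counts drawn from the means, dispersions and library sizes of the 16202 features. Each feature was drawn independently around 1 mean, without batch effects or variation shared between features. The real libraries hold such shared variation, so the shares below may not hold for them. For size, 81.0% of 100 features changed by 2 log2 units and 30.0% of 100 changed by 1 log2 unit were recovered. For scent the shares were 72.0% and 11.0%. For the interaction they were 10.0% and 0%, and for age 52.0% of 100 features changed by 0.2 and 3.0% of 100 changed by 0.1 log2 units per unit of age were recovered. Calls of unchanged features numbered 9 of 120 for size, 5 of 60 for age, 2 of 85 for scent and 0 of 10 for the interaction, so the share of false calls for size and age lay above the 0.05 aimed at in this single simulation.

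Alternatives fixed before the data were examined were DESeq2 1.42.0 (Wald test) and DESeq2's size factors, limma-voom with batch as a random block, scent and batch without size class, other filters on low counts, no robust shrinkage, no batch term, RIN or age as covariates, weight in kg as a slope, batches 1, 3 and 6 alone, 1 dog per breed, the deposited log2 table tested with limma, and each dog left out in turn. Chosen after seeing the data were the covariates for the chromosome-named total, the chromosome 5 and 21 total and the library total, the removal of the 3 libraries with the lowest TMM factors, and all measures of the chromosome-named features. DESeq2 was run without the low-count filter of the main test. Its adjusted p covered 27482 features for scent, 18518 for size, 21682 for age and 25384 for the interaction. Its calls are therefore not on the same 16202 features as those of edgeR.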

Results

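The study profiled gene expression in the olfactory epithelium of 17 dogs in relation to olfaction. Of these dogs, 10 carried scent code 0 (scent_0) and 7 scent code 1 (scent_1). By weight class, 8 were labelled Below_10 (5.0 to 9.79 kg) and 9 Over_10 (10.21 to 44.0 kg). The factors were not balanced, with 6 Below_10 and 4 Over_10 dogs in scent_0 and 2 Below_10 and 5 Over_10 dogs in scent_1. Both Below_10 dogs of scent_1 were dachshunds, and both Labrador retrievers were in scent_1. Labelled age ran from 0.5 to 14 and RIN from 5.9 to 9.1. Batches 1, 3 and 6 held both scent codes and batches 2, 3, 4 and 6 both weight classes. Batch 5 held a single dog, the youngest. No difference in library totals was shown between weight classes (log2 total 23.72 ± 0.50 in 9 Over_10 and 23.69 ± 0.51 in 8 Below_10 dogs, SD; exact permutation p = 0.949).

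In 3 libraries a few features took a larger part of the counts. The 10 most abundant features held 26.5% of the counts in scent_1 replicate 1 (dachshund, RIN 5.9), 19.8% in scent_0 replicate 3 (cocker spaniel) and 18.2% in scent_0 replicate 1 (Pomeranian), against 5.94% to 10.3% in the other 14. These 3 had the lowest TMM factors (0.518, 0.757 and 0.727) and the lowest scores on the first principal component, which held 38.0% of the variance. Mean scores on the second component (22.6% of the variance) differed between weight classes, at 30.4 ± 22.1 (SD) in 9 Over_10 and -34.2 ± 46.4 in 8 Below_10 dogs (two-sided exact permutation p = 0.00271). The classes overlapped, since scent_1 replicate 1 and scent_0 replicate 1, both Below_10, scored 24.4 and 31.3, and scent_1 replicate 5, an Over_10 dog, scored -10.0. The difference between scent codes on it did not pass (exact permutation p = 0.143).

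**Figure D1:**
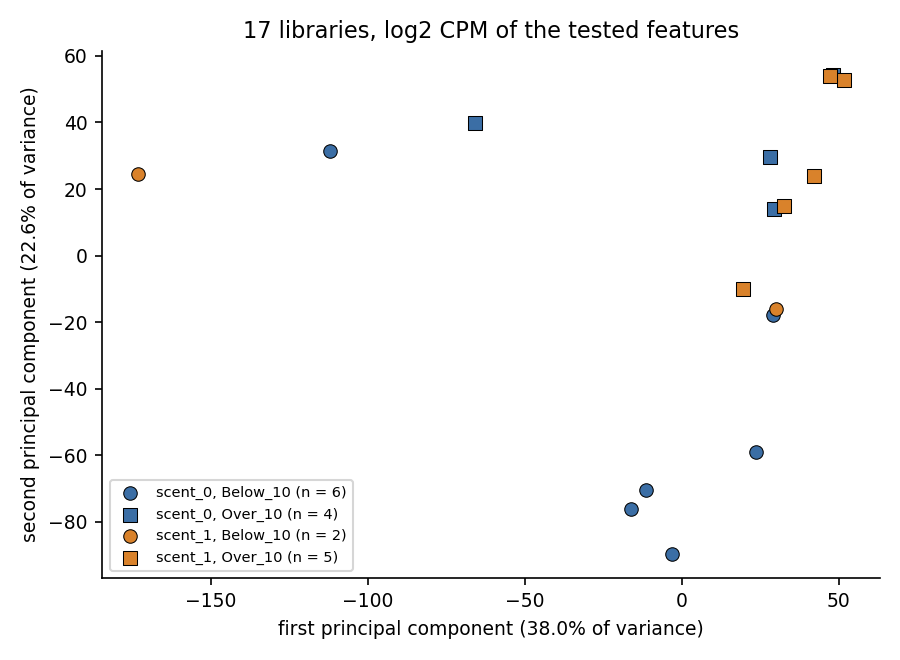
First against second principal component of log2 CPM for the 17 libraries (scores without unit), coloured by scent code and shaped by weight class. The 3 libraries at the left lie between -173 and -65.9 on the first component, and the 4 lowest scores on the second, from -89.7 to -59.1, are Below_10 dogs.

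A group of 208 features named for a chromosome and a running number stood beside the Ensembl-style gene IDs. Chromosomes 18, 21, 20, 14, 5 and 27 held the most, with 45, 44, 16, 13, 12 and 10 features. The same chromosomes hold 196, 199, 74, 41, 44 and 38 olfactory receptor genes in the RefSeq table of assembly UU_Cfam_GSD_1.0. Across 39 chromosomes the number of such features followed the number of olfactory receptor genes (Spearman's rho = 0.87, permutation p = 1e-05, the smallest that 100000 permutations can give). It followed the number of protein-coding genes with a lower rho (rho = 0.32, permutation p = 0.0432). Chromosomes are not independent replicates. These features held between 0.00489% of a library's counts (598 reads, 95% Wilson interval 0.00451 to 0.00530, scent_1 replicate 6, basset hound) and 0.0930% (9858 reads, interval 0.0912 to 0.0949, scent_0 replicate 1).

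The scent comparison asks which transcripts differ between dogs of the 2 scent codes, the labelled factor closest to the study's subject. No feature passed edgeR's test, with 288 at an unadjusted p under 0.05, whereas DESeq2 called 9. Among the chromosome-named features, 76 of 90 tested had a fitted value below 0 in scent_1 (median log2 fold change -0.93), and 0 were called either way, also when adjusted over the list alone. Their summed level was 405 ± 571 CPM (SD, n = 7) in scent_1 and 457 ± 364 CPM (n = 10) in scent_0, with medians of 250 and 356 CPM. A single library, scent_1 replicate 1 with 1683 CPM, carried the scent_1 mean, which was 193 ± 101 CPM (n = 6) without it. The log2 totals, 7.82 ± 1.61 and 8.43 ± 1.18, differed by less than the spread between dogs (exact permutation p = 0.375, adjusted p = 0.375). Without scent_1 replicate 1 the log2 difference went from -0.61 to -1.10 (exact permutation p = 0.0835), and without scent_1 replicate 6 to -0.22 (exact permutation p = 0.734). The detected number was 82.6 ± 42.4 in scent_1 and 105 ± 40.8 in scent_0 (exact permutation p = 0.278, adjusted p = 0.370). Within batches the difference in the detected number was -46.2, about 2 times the -22.7 over all dogs, and did not pass (exact permutation p = 0.0667 over 60 splits, adjusted p = 0.133). It was -29 in batch 1, -35 in batch 3 and -59.7 in batch 6, but these values mix scent with weight class. Among dogs of 1 batch and 1 weight class the difference was -29 in batch 1 (Below_10, 1 dog each), 6 in batch 3 (Over_10, 1 dog each) and -23 in batch 6 (Over_10, 2 scent_1 dogs and 1 scent_0 dog).

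Of 16202 features tested with edgeR's quasi-likelihood test, 0 were called between scent codes. DESeq2, run without the low-count filter on a larger set of 27482 features, called 9. With edgeR 288 had an unadjusted p under 0.05, where chance gives 810.1 on average. In random splits of the dogs this number ran from 132 to 3698, so 288 is within what chance gives. With the library total as a covariate edgeR called 2, with 2194 at an unadjusted p under 0.05. Without the 3 libraries with the low TMM factors 0 were called and 1005 had such a p, as did 822 without scent_1 replicate 1 and 806 without scent_0 replicate 1. Camera placed the chromosome-named features lower in scent_1 at its preset correlation (adjusted p = 8.8e-04), and so the sets of chromosomes 27 and 18 (adjusted p = 0.0155 and 0.0462). With an estimated correlation the adjusted p was 0.846, 0.585 and 0.846, and fry gave 0.828 for each. Within batches the log2 total differed by -1.17 (exact permutation p = 0.133 over 60 splits), with 0.39 in batch 1, -0.27 in batch 3 and -2.31 in batch 6. Within 1 weight class of these batches it differed by 0.39, 0.69 and -1.95, so no direction was common to them.

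The size comparison asks which transcripts differ between small and large dogs. Weight class went with 1448 of the 16202 features, of which 863 were higher and 585 lower in Over_10 dogs. Among the higher features 578 changed by over 2-fold and 156 by over 4-fold, and among the lower features 368 and 57 did so. The median change was 1.28 log2 units for the higher and 1.16 for the lower features. At an unadjusted p under 0.05 there were 4312 features, where chance gives 810.1 on average. This number varies widely by chance, since features move together: in random splits of the dogs it ran from 99 to 5166.

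The IDs with the smallest p changed more than the median called feature (1.28 log2 units for the higher and 1.16 for the lower), so their sizes are not typical. ENSCAFG00000023202 rose from 12.6 ± 12.2 CPM (SD, n = 8) in Below_10 to 27.6 ± 10.4 CPM (n = 9) in Over_10 dogs, a fitted log2 change of 2.20 ± 0.28 (SE; edgeR adjusted p = 0.0165). ENSCAFG00000010794 rose from 21.5 ± 21.2 to 36.1 ± 8.16 CPM (log2 change 1.78 ± 0.24, edgeR adjusted p = 0.0165). In the other direction ENSCAFG00000015833 fell from 3.72 ± 3.04 to 0.491 ± 0.804 CPM (log2 change -4.64 ± 0.43, edgeR adjusted p = 0.00181). ENSCAFG00000028658 fell from 5.09 ± 4.05 to 0.774 ± 1.13 CPM (log2 change -4.09 ± 0.54, edgeR adjusted p = 0.0165). Both lay near the floor in Over_10 dogs, at 0.0786 to 0.513 and 0.0786 to 1.17 CPM apart from scent_1 replicate 5. ENSCAFG00000015833 passed the low-count filter in only 12 of the 17 fits without 1 dog. The size of these 2 falls is therefore uncertain. The fitted changes compare dogs within batches, whereas the means run over all dogs, so they are not ratios of each other. The 2 Below_10 dogs of batch 1 lay on the Over_10 side or beyond for ENSCAFG00000010794 (60.1 and 49.9 CPM, above every Over_10 dog), ENSCAFG00000015833 (0.733 and 0.260 CPM) and ENSCAFG00000028658 (0.428 and 0.780 CPM). Without scent_0 replicate 7 the first, second and last of these had log2 changes of 2.03, 1.86 and -3.96 and an adjusted p of 0.0613. Without the batch term the first 2 went to 1.08 and 0.67 (adjusted p = 0.186 and 0.353) and the last to -3.45 (adjusted p = 0.0584). With the chromosome 5 and 21 total as a covariate the log2 changes were 2.40, 2.14, -4.34 and -3.35, with an adjusted p of 0.0900 for the first 3 and 0.0945 for the last.

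The directions of the called features held within batches, on the same data that selected them. In batch 2 (2 dogs of each class), 863 of the higher and 585 of the lower features went the fitted way, in batch 3 861 and 581, in batch 4 (1 dog of each class) 819 and 551, and in batch 6 862 and 585. The number called depended on single dogs: 1 without scent_0 replicate 7 (bulldog terrier, 3429 at an unadjusted p under 0.05), and 125, 129, 195, 381 and 410 without scent_0 replicates 9, 6, 2, 4 and 10. Those of the 1448 features that these fits tested all kept their sign. Their median fold was 0.949 times the main one without scent_0 replicate 7 and 0.933 to 1.01 times in the others, again on the data that selected them. It also moved with the model, to 168 without the batch term, 100 with log2 weight as a slope (28 rising and 72 falling with weight, against the 863 and 585 between classes), 555 with 1 dog per breed, 2354 in the deposited log2 values, 3164 with DESeq2 and 3130 with the library total as a covariate. With the total of the chromosome 5 and 21 features as a covariate edgeR called 0, with 3844 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0900, and DESeq2 was not run with it. Without the 3 libraries with the low TMM factors, 1653 were called.

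**Figure D2:**
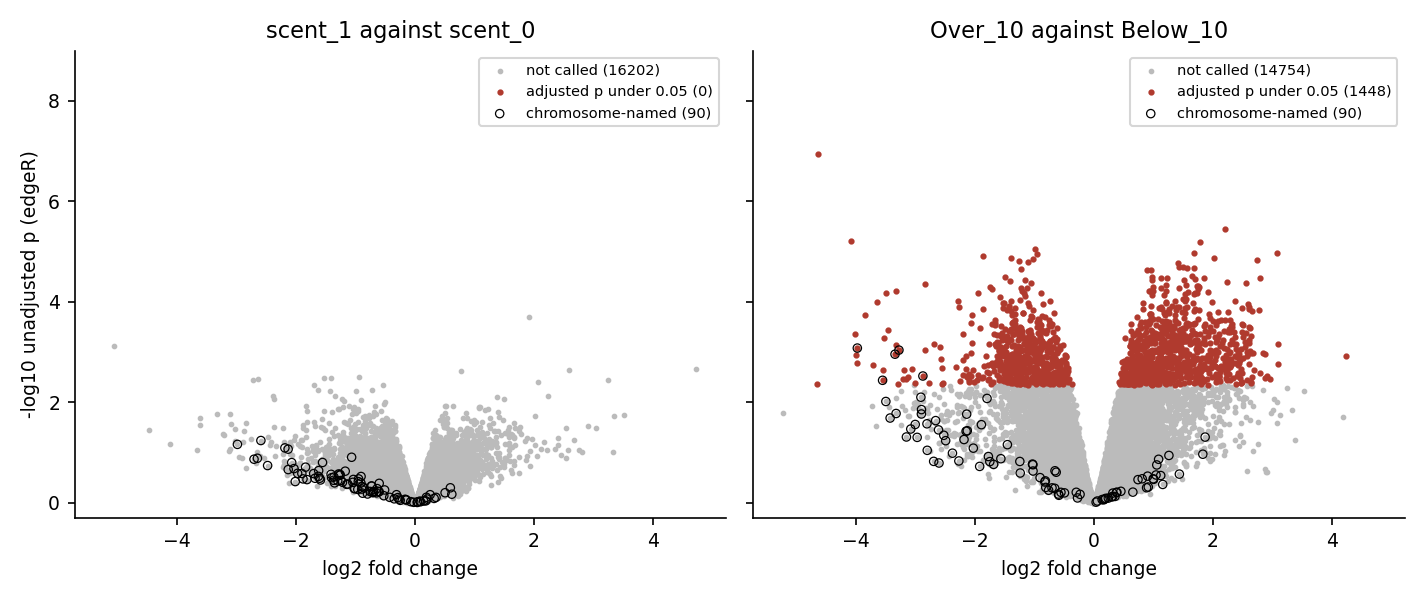
Fitted log2 fold change (horizontal) against -log10 of the unadjusted edgeR p (vertical) for 16202 features, for scent codes at the left and weight classes at the right. Red points are called at an adjusted p under 0.05, 0 for scent and 1448 for size, and open circles mark the 90 chromosome-named features.

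Chromosome-named features were less widely detected in large dogs. After thinning to equal depth, 128 ± 16.1 (SD, n = 8) were detected in Below_10 and 67.7 ± 36.8 (n = 9) in Over_10 dogs. Every Below_10 dog had at least 110, whereas 7 of the 9 Over_10 dogs had between 31 and 64. The other 2 Over_10 dogs were scent_0 replicate 3 (cocker spaniel, 12.247 kg) with 124 and scent_1 replicate 5 (Labrador retriever, labelled age 0.5) with 134. Both are among the 4 libraries marked as a first replicate and had the highest totals of the Over_10 dogs, 29240086 and 20809138 counts. Scent_1 replicate 2, an Over_10 dog with the same mark and 12664228 counts, had 62. Whether the mark or the dog made these 2 exceptions was not tested. The difference between weight classes passed over all splits (two-sided exact permutation p = 0.00165, adjusted p = 0.00658) and within batches (exact permutation p = 0.00556, adjusted p = 0.0222). The difference in means, Over_10 minus Below_10, was -43 in batch 2, -79 in batch 3, -60 in batch 4 and -70.3 in batch 6.

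The summed level was 654 ± 543 CPM (SD, n = 8) in Below_10 and 242 ± 216 CPM (n = 9) in Over_10 dogs, with medians of 394 and 183 CPM. The 3 libraries with the low TMM factors held the 3 highest totals of all 17 (1683, 1281 and 770 CPM), and without them the means were 377 ± 177 CPM (n = 6) and 176 ± 92.4 CPM (n = 8), a log2 difference of -1.21 (exact permutation p = 0.0196). On the log2 scale the totals were 8.96 ± 1.12 and 7.48 ± 1.20, a 2.77-fold difference (exact permutation p = 0.0204, adjusted p = 0.0407). With 1 dog per breed the log2 difference was -1.13, which did not pass (exact permutation p = 0.0721). Within batches the total was 2.08-fold higher in Below_10 dogs, which did not pass (exact permutation p = 0.111, adjusted p = 0.133), and batch 2 showed a difference of 0.07 log2 units the other way.

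**Figure D3:**
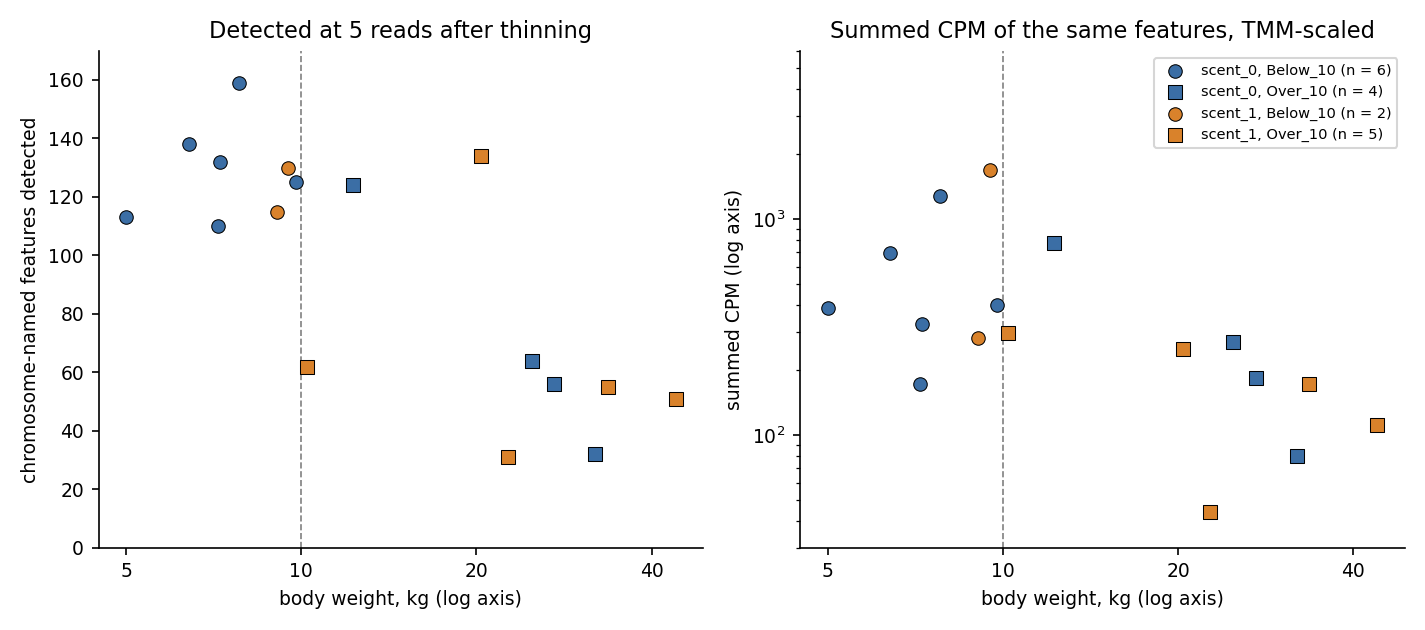
Number of chromosome-named features with at least 5 reads after thinning (left) and their summed TMM-scaled CPM (right, log axis) against body weight in kg (log axis), 1 point per dog, with a dashed line at 10 kg. All 8 Below_10 dogs have 110 to 159 detected features, and 7 of 9 Over_10 dogs have 31 to 64.

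By chromosome, the features of chromosome 5 summed to at least 13.1 CPM in each Below_10 dog and to at most 1.25 CPM in 7 of the 9 Over_10 dogs. Chromosome 21 features summed to at least 27.0 CPM in each Below_10 dog and to at most 11.4 CPM in the same number of Over_10 dogs. Scent_0 replicate 3 and scent_1 replicate 5, both marked as a first replicate, were again the exceptions on both chromosomes. The mean log2 levels were 4.59 ± 1.13 and 1.02 ± 1.90 for chromosome 5, an 11.8-fold difference, and 5.86 ± 1.19 and 2.91 ± 1.66 for chromosome 21, a 7.70-fold difference (SD, n = 8 Below_10 and n = 9 Over_10; exact permutation adjusted p = 0.0132 for both). The chromosome 5 fold depends on the added 0.5 CPM, which is close to the level of most Over_10 dogs. Without a log its means were 34.5 and 4.77 CPM and its medians 19.5 and 0.601 CPM. Of the 44 chromosome 21 features, 23.9 ± 8.03 (SD, range 16 to 37) were detected in Below_10 and 7.11 ± 11.1 (range 1 to 34) in Over_10 dogs. In the 7 Over_10 dogs at most 3 were detected, but their low detected number, by which they were picked, includes these features. In that RefSeq table chromosome 21 holds 163 receptor genes of class I, the receptor class known as fish-like, and the other chromosomes hold 0.

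Chromosome 20 features were 2.47-fold higher in Below_10 dogs (exact permutation adjusted p = 0.0456). Chromosomes 14, 18 and 27 and the unplaced features did not pass, with folds of 1.87, 2.14, 1.66 and 1.77 and exact permutation adjusted p of 0.355, 0.355, 0.446 and 0.355. Within batches the folds were 10.9 for chromosome 5 (again dependent on the added 0.5 CPM), 6.91 for chromosome 21 and 2.08 for chromosome 20. None of these passed the adjustment over the 16 tests, with exact permutation p of 0.00833, 0.00556 and 0.0639 and adjusted p of 0.0667, 0.0667 and 0.256. The smallest p that the 360 within-batch splits can give is 0.00278.

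**Figure D4:**
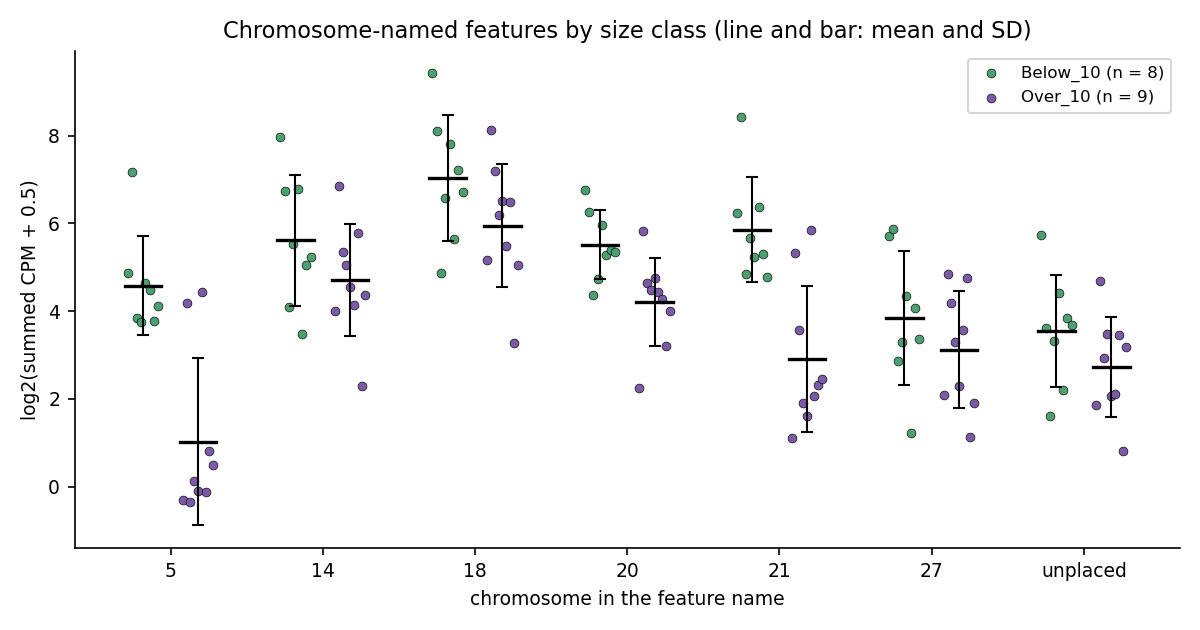
Log2 of the summed CPM plus 0.5 of the chromosome-named features, by the chromosome in the feature name, for 8 Below_10 and 9 Over_10 dogs. Points are dogs, and lines and bars are means and SD, with the largest differences in means on chromosomes 5 (4.59 against 1.02) and 21 (5.86 against 2.91).

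In the test of single features, 5 of the 90 tested chromosome-named features were called lower in Over_10 dogs and 0 higher, and adjusted over the list alone 3 were lower. This share, 5.56%, was not shown to differ from the 3.60% of the other features called lower (two-sided Fisher's exact p = 0.262), and 0 of 90 were called higher against 5.36% of the others (p = 0.0153). Fisher's test takes features as independent, but the correlation estimated among the 90 was 0.45, so its p is too small by an unknown amount. Of the 90, 59 had a fitted value below 0, and the median log2 fold change was -0.82. All 10 tested chromosome 21 features had a fitted value below 0 (median -2.71), as had all 4 of chromosome 5 (median -2.59). The medians were above 0 for chromosomes 14 (0.35, 4 of 10 below 0), 15 (0.19, 2 of 5) and 27 (0.82, 1 of 4), none of which passed, although the mean totals of chromosomes 14 and 27 over all dogs were higher in Below_10, also without passing. Camera called all 90 lower (adjusted p = 4.8e-06), and the sets of chromosomes 21, 5 and 20 (adjusted p = 4.8e-06, 0.00866 and 0.0364). With an estimated correlation none passed, with adjusted p of 0.643, 0.598, 0.598 and 0.643 in that order. Fry, which asks whether a set moves one way, gave adjusted p of 0.0154 for chromosome 21, 0.0416 for chromosome 5 and 0.249 for all 90.

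Over the 17 dogs the total of the chromosome-named features fell with log2 body weight (Pearson's r = -0.63, permutation p = 0.00611, adjusted p = 0.0183; Spearman's rho = -0.63, permutation p = 0.00715, adjusted p = 0.0214). Without the 2 dogs farthest from the median weight r was -0.59 (permutation p = 0.0210), and with batch means removed it was -0.63. In the 9 Over_10 dogs r was -0.61 (exact permutation p = 0.0820) and in the 8 Below_10 dogs 0.22 (exact permutation p = 0.608). Detected numbers fell into 2 separate ranges, so no pooled r is given for them. Within the 9 Over_10 dogs r of the detected number with log2 weight was -0.49 (exact permutation p = 0.162; rho = -0.57, exact permutation p = 0.121), and within the 8 Below_10 dogs 0.14 (exact permutation p = 0.731; rho = 0.14, exact permutation p = 0.752).

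For age and RIN the relation with the total did not pass. For labelled age r was -0.06 (permutation p = 0.814, adjusted p = 0.973; rho = -0.07, permutation p = 0.783, adjusted p = 0.783) and 0.02 without the 2 dogs farthest in age, and for RIN r was -0.34 (permutation p = 0.184, adjusted p = 0.368; rho = -0.12, permutation p = 0.651, adjusted p = 0.782) and 0.11 without the 2 dogs farthest in RIN. Adjustment ran over 6 relations. With batch means removed r was 0.12 for age and -0.06 for RIN.

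Age was tested as a slope per labelled unit, and the interaction as a scent difference that itself differs between weight classes. Neither gave a call with edgeR, and no set of chromosome-named features passed for age (smallest camera adjusted p = 0.129). For age, edgeR called 0 features, with 686 at an unadjusted p under 0.05. DESeq2, without the low-count filter, called 93 of 21682, of which 87 rose with age. Without scent_1 replicate 3 edgeR called 2, and without scent_1 replicate 4 it called 4. With the library total as a covariate it called 1. For the interaction, edgeR called 0 features, with 936 at an unadjusted p under 0.05, and DESeq2 called 30 of 25384. In batches 1, 3 and 6 alone edgeR called 1, with 3250 at an unadjusted p under 0.05, and without the batch term it called 0, with 1908 at such a p. Only 2 dogs, both dachshunds, were Below_10 in scent_1, and the simulated interaction of 2 log2 units was recovered for 10.0% of 100 features.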

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

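The tests of explanations in this part were chosen after the result was seen, except the removal of the 10 most abundant features. In 36 groups of values, each of 7 to 10 dogs, 11 held a dog whose gap to its neighbour took up most of the range. Chance would give about 1.8 for independent groups of normally distributed values. Library totals and the CPM of the features named by ID were screened without a log, so an excess over chance is not shown. The groups overlap, since each dog has a scent code and a weight class.

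Depth set 2 dogs apart. Scent_0 replicate 3 had 29240086 counts, against 13209206 in the next of the 10 scent_0 dogs, and scent_1 replicate 1 had 31637925 counts, against 13209206 in the next Below_10 dog. Both are among the 4 libraries marked as a first replicate, and it is not given whether these hold pooled or single extractions. The same 2 dogs stood apart in composition. The TMM factor was 0.518 in scent_1 replicate 1, next to 1.03 in scent_1, and 0.757 in scent_0 replicate 3, next to 1.03 in Over_10. The 10 most abundant features took 26.5% of the counts in scent_1 replicate 1 and 19.8% in scent_0 replicate 3, with 10.3% next in both groups.

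With scent_0 replicate 1 these made up 3 libraries with the lowest scores on the first component. Their distance was not confined to the few features that took most of the counts. With a common shift taken out, the median absolute deviation of each library from the mean of the other libraries outside the 3, over all 16202 features, was 0.60 to 1.19 log2 units in the 3 and at most 0.38 in the other 14, a ratio of at least 1.59. The 3 were picked on measures of these same counts and left out of the reference, so their larger deviation is no independent test. A median of this size shows only that the distance was spread over many features. Removing the 10 most abundant features moved the distance of the nearest of the 3 from the others from 3.21 to 3.20 SD, too little of the 16202 features to decide anything. Library depth and RNA integrity as causes shared by all 3 are argued against, since 1 of the 3 totals and 2 of the 3 RIN values lay within the range of the other 14 libraries. For single libraries both stay open. Scent_1 replicate 1 and scent_0 replicate 3, both marked as a first replicate, had the highest totals of all libraries. Scent_1 replicate 1 also had the lowest RIN, 5.9. The batch stays open, since 2 of the 3 are all of batch 1, and a different mixture of tissue in the sampled piece may too, which was not tested because cell type lists need gene names. Neither scent (exact permutation p = 0.714) nor weight class (exact permutation p = 0.0620) passed on the first component, which does not show that the groups were alike on it.

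Among the features named by ID, ENSCAFG00000023202 stood at 41.5 CPM in scent_0 replicate 1, next to 15.0 CPM in Below_10, above the Over_10 mean. ENSCAFG00000015833 and ENSCAFG00000028658, both lower in Over_10 dogs, stood at 9.22 and 9.56 CPM in scent_1 replicate 3 (dachshund), next to 2.60 and 3.66 CPM in scent_1. Within Over_10 the highest values of these 2 features, 2.60 and 3.66 CPM, were both in scent_1 replicate 5, the youngest dog, next to 0.513 and 1.17 CPM. That dog is the only one of its batch and bears on no size coefficient.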

How the results depend on the processing

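Settings chosen after seeing the data were the added chromosome-named and library totals, the removal of 3 libraries and all alternatives of the chromosome-named measures. The size call moved most. DESeq2, run without the low-count filter, called 3164 of 18518 features, all 1448 among them. The library total as a covariate gave 3130, again with all 1448, and limma on the deposited log2 values 2354 (1414 shared). With 1 dog per breed 555 were called (518 shared), without the batch term 168 (154 shared) and with log2 weight as a slope 100 (72 shared; 28 rising and 72 falling, the opposite balance to 863 and 585). With the chromosome 5 and 21 total added 0 were called by edgeR, with 3844 at an unadjusted p under 0.05. Leaving out 1 dog gave 1 to 1985 calls. The lowest was without scent_0 replicate 7, and 125, 129, 195, 381 and 410 came without scent_0 replicates 9, 6, 2, 4 and 10. The number with an unadjusted p under 0.05 was between 3429 and 4804 in these 17 fits. In each of them the called features that it tested kept their sign. Their median fold was 0.933 to 1.10 times the main one, on the data that selected them. The other 11 settings and the other 11 fits without 1 dog stayed within 1.5 times of 1448 in total. Their directions and members moved more: batches 1, 3 and 6 alone gave 906 higher and 297 lower (632 shared), limma-voom 1140 and 611 (957 shared), and the fits without scent_0 replicates 3 and 8 gave 903 lower and 532 higher. The 4 features named by ID kept their sign in every weight class fit that tested them, which for ENSCAFG00000015833 were 12 of the 17 without 1 dog and 16 others. Of these, 3 lost their call without scent_0 replicate 7 (adjusted p = 0.0613), the same 3 lost it without the batch term, where ENSCAFG00000023202 went from 2.20 to 1.08 and ENSCAFG00000010794 from 1.78 to 0.67, and all 4 lost it with the chromosome 5 and 21 total.

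For scent, DESeq2 called 9 features and the library total as a covariate gave 2. The other 16 settings, by edgeR, limma-voom or limma, and each of the 17 edgeR fits without 1 dog gave 0 (164 to 822 at an unadjusted p under 0.05 without 1 dog). For age, DESeq2 called 93 and the library total gave 1, with 0 to 4 calls when 1 dog was left out, 2 without scent_1 replicate 3 and 4 without scent_1 replicate 4. For the interaction, DESeq2 called 30 and batches 1, 3 and 6 alone gave 1, with 0 calls when any 1 dog was left out (623 to 1944 at an unadjusted p under 0.05 with edgeR).

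The log2 total of the chromosome-named features by size changed from -1.47 to -1.06 within batches (exact permutation p = 0.111) and to -1.13 with 1 dog per breed (exact permutation p = 0.0721), both without passing. It stayed between -1.73 and -1.22 when 1 dog was left out. The detected number by size differed by -68.4 to -55.5 without 1 dog (exact permutation p at most 0.00533) and passed under all 6 other settings. By scent, the total (-1.10 to -0.22 without 1 dog) and the detected number (-31.3 to -14.1 without 1 dog) passed in none of these fits or other settings, of which the within-batch values lay farthest from 0, at -1.17 and -46.2 (exact permutation p = 0.133 and 0.0667). Apart from the fewer dogs used in some settings, and the chromosome 5 and 21 total, whose overlap with weight class is given under the other observations, the cause was not tested. Alternatives set out for gene lists, olfactory neuron markers and named olfactory receptors were not run, for want of gene names. No paired analysis was possible because replicate numbers only name dogs. Depth limits the detected number, since features under 5 reads at 10536639 counts were counted as absent.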

Other observations

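Of the tests in this part, the splits of the dogs and the fits with the library total and with the chromosome 5 and 21 total were set out before their results were seen, although both covariates were added after the data had been seen, and all others were chosen after the result was seen. The spread of reads over the chromosome-named features was described without a test. Between 14 and 26 features held the first 50% of these reads in the 8 Below_10 dogs. In the 7 Over_10 dogs with few detected features, 7 to 16 did, and in scent_0 replicate 3 and scent_1 replicate 5 it took 17 and 31. The detected number by chromosome shows where these 7 Over_10 dogs, picked for their low detected number, lacked features. Of 12 chromosome 5 features, 6 to 11 were detected in each Below_10 dog and 0 or 1 in the 7 Over_10 dogs, whereas of 13 chromosome 14 features 6 to 13 were detected in Below_10 and 2 to 9 in those 7 dogs. Over all 9 Over_10 dogs the ranges were 0 to 12 on chromosome 5 and 2 to 13 on chromosome 14.

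A hypothesis is that these features are olfactory receptor gene models. Their number per chromosome followed the RefSeq receptor count (rho = 0.87), more closely than the protein-coding count (rho = 0.32), and 192 of the 193 placed features lie on a chromosome with at least 1 receptor gene. The highest running number exceeded the receptor count on 2 of the 23 chromosomes with such features. No sequence or name ties a single feature to a receptor here.

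Large dogs had a lower total of these features over all splits, a difference that did not pass within batches (exact permutation p = 0.111). No difference in log2 library totals was shown between weight classes (exact permutation p = 0.949), which gives no sign of depth as a source. The detected number at equal depth was also lower (difference -60.1, SE 13.5), but it is another measure and does not test the total. RNA integrity does not account for the lower total, as the size difference kept 0.938 of its value with RIN taken into account. Nor do the 3 libraries that stood apart, without which it kept 0.824 of its value. Body size, breed and the part of the epithelium that was sampled all stay open and were not tested against each other.

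A hypothesis is that the fall was unequal across chromosomes, and the site of sampling may be a source of it, since expression of receptor genes is known to follow zones of the epithelium. If a single factor lowered all of these features alike, the ratio of chromosome 21 to the others would not differ between weight classes. The log2 ratio was -4.49 ± 1.39 (SD, n = 9) in Over_10 and -2.87 ± 1.19 (n = 8) in Below_10 dogs. The exact permutation p was 0.0245 over all splits and 0.0222 within batches, but 0.0979 and 0.119 after adjustment over 16 tests. This ratio therefore does not tell a common factor from an unequal fall at this number of dogs, and the site of sampling was not tested. The explanation judged by the ratio was first put as a fall specific to chromosome 21 and judged by the unadjusted p. It was reworded with the adjusted p after both had been seen. By dog, 7 of the 9 Over_10 totals lay below every Below_10 total on chromosome 5, and 7 on chromosome 21. On chromosome 20 it was 4, and on chromosomes 14, 18 and 27 and among the unplaced features 1 each. This contrast between chromosomes was not tested.

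The size difference across all features was set against other groupings of the dogs. Of 100 splits, the real one included, 2 gave at least as many calls as weight class. Such a count was rare among random splits but did arise in 1 of them. The other of the 2 gave 3018 calls against the real 1448, and after batch and scent its labels followed the first component (absolute r = 0.906), along which the 3 libraries with low TMM factors stood apart. A split with more calls than the real one points to a structure of the samples besides weight class. Among 100 splits that keep each batch's numbers 1, the real one, reached 1448, and the highest other gave 1. With 100 splits the lowest share possible is 1 of 100, so chance was made unlikely there but not excluded. For scent the real count was 0, so all 100 splits reach it by construction and decide nothing, and the highest other gave 2.

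With the total of all chromosome-named features in the model the median fold of the 1448 features called by size kept 0.947 of its size. With RIN it kept 1.01, and with the library total, as a measure of depth, 1.00. None of these covariates took up the fold of these features, which were selected on the same data. With the chromosome-named total edgeR called 1034 features, 793 of the 1448 among them. A difference in tissue share that this total does not follow stays open. With the chromosome 5 and 21 total the median fold of the called features was 1.37 log2 units (median SE 0.45) against 1.22 (median SE 0.28), a ratio of 1.12, yet edgeR left 0 calls (3844 at an unadjusted p under 0.05). The calls ended because the error grew, since this covariate shared 61.0% of its variance with weight class after batch and scent. A ratio above 0.75 had been set beforehand as evidence against this explanation and was met, but that bound was wrong for a covariate so close to weight class, and the verdict was changed to open after the result was seen. Whether the size difference may come from the same tissue difference as those features, or from body size itself, cannot be told apart.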
